A study of Homo sapiens with 6 samples.

How the data were processed

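Total RNA was extracted with Trizol from stable THP-1 cells, libraries were made with standard Illumina protocols and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The series holds 6 libraries, 3 of SRSF10 knockdown cells and 3 controls, grouped here by the genotype label. FastQC, Trim Galore and the GRCh38 build are named in the submitters' processing notes. The aligner, the read counter, its strand setting and the statistical test of the authors are not given in the sources used here.

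The authors deposited values for 15791 genes in a single table, with an RPKM value for each library, a gene length, the exon coordinates and their own comparison. Per the file headers the library values are RPKM, and RPKM multiplied by gene length came out as a whole number of reads, within 0.01 reads, for 100.0% of the values in every library. The depth recovered in this way was 33268327 to 41276948 assigned reads per library, of which 99.74 to 99.79% belong to the genes listed. Each read in a gene of 1 kb is worth 0.0242 to 0.0301 RPKM, so a short gene near 0.5 RPKM rests on few reads and is measured less precisely than a longer gene at the same RPKM. The authors' deposited table also gives a log2 fold change, a p-value and an FDR (an adjusted p-value) per gene. The direction and base of that log2 column were checked against the RPKM means. The authors had removed weakly expressed genes before deposit, by a rule not given in the sources used here.

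RPKM values are not counts, so the test was limma 3.58.1 with an intensity trend (trend = TRUE) in R 4.3.3, on log2(RPKM + 0.5) over the 14223 genes with at least 0.5 RPKM in at least 3 libraries. The model compared 3 knockdown with 3 control libraries without covariates. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was the threshold. The planned design named one test for counts and this one for RPKM, and the table holds RPKM. Simulated data gave every gene the median spread of these libraries, drew genes independently and changed 200 of 14223 genes. On them the procedure recovered 17.6% of genes changed 1.25-fold, 79.6% at 1.5-fold, 100% at 2-fold and 97.6% at 4-fold, and 7.3% of its calls were false. The simulation leaves out the variation shared across genes that the real libraries show, and changes far fewer genes than were called. These rates may therefore not hold for the real data.

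The genes named in the text were chosen by a rule fixed before the data were examined, as were the groups, the tests, the gene lists and most of the other settings tried. The rule took SRSF10, then the 10 genes with the largest log2 fold change in each direction among those with an adjusted p under 0.05, a mean of at least 1 RPKM in 1 group and no overlap between the libraries of the groups. It then took up to 3 members of each list with the smallest adjusted p and 1 abundant member that did not pass. Pseudogenes, genes without a symbol and near-identical gene copies were passed over. Some genes that the rule took are not reported here. Any gene named outside this rule was chosen after its values were seen. Of the 41 lists, 33 had at least 5 tested members and were tested with camera in limma at a preset correlation of 0.01, adjusted over those 33 lists. Of these, 8 were called, and none was called with an estimated correlation. The fry test, which asks whether the genes of a list move one way on balance and does not compare them with other genes, called 21.

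Coordinates are those of the authors' deposited table. Gene types and names came from GENCODE release v44 on the same build, with 12655 gene names matched by symbol, 614 by an older symbol and 2522 not matched. GC content was computed from the exon coordinates for 100% of genes. Exon overlap between rows was computed because reads of overlapping or antisense genes cannot be told apart here, and 1367 genes share at least 50% of their exon sequence with another row. Replicates were compared before averaging. All pairs within a group differed by more than sampling noise (chi-square of 6.71 to 41.3 per gene), so each library was counted as 1 replicate.

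Other settings fixed in advance were quantile normalisation, median centring, pseudocounts of 0.1 and 1, no filter, a filter of at least 1 RPKM in all 6 libraries, a replicate block, leaving out each library in turn, limma without the trend, protein-coding genes only, and for lists an estimated correlation and fry. Scaling to non-mitochondrial reads, limma-voom on the recovered reads and a smooth correction for GC content and gene length (mgcv 1.9.3) were chosen after seeing the data. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and version 1.17.8 of data.table.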

Results

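Messenger RNA levels were compared between 3 libraries of THP-1 cells in which SRSF10 had been knocked down and 3 control libraries labelled wild type. THP-1 is a human monocytic line derived from acute myeloid leukaemia, and the RNA came from stable cells. SRSF10 is a serine- and arginine-rich RNA-binding protein that regulates the splicing of precursor mRNA. The series asks which transcripts differ in level once SRSF10 is reduced. Reads assigned to genes numbered 41020837, 37937356 and 38149796 in controls 1 to 3 and 38685453, 41276948 and 33268327 in knockdowns 1 to 3. Values below are RPKM (assigned reads scaled to gene length and to the assigned reads of the library), given as mean ± SD with n = 3 libraries per group unless another n is stated. Fold changes are on the log2(RPKM + 0.5) scale, knockdown over control, which understates the change of weakly expressed genes. The sources do not state that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

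SRSF10 itself stood at 19.4 ± 1.61 RPKM in the controls and 5.33 ± 0.831 RPKM in the knockdowns (SD, n = 3), 27.4% of the control level. The gene lies on the minus strand of chromosome 1, from 23964804 to 23980927 (GRCh38), and is annotated as protein-coding. The 3 controls gave 17.6, 20.7 and 20.02 RPKM and the 3 knockdowns gave 4.37, 5.83 and 5.79 RPKM, from 1738 to 8062 reads per library, so the 2 groups did not overlap. The log2 fold change was −1.78 (SE 0.118), with a Benjamini-Hochberg adjusted p of 0.000238 in limma. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 against 3 libraries allow. The authors' deposited table gives a log2 fold change of −1.75 for SRSF10 with an FDR of 3.2e-06. The description field of the control samples also names SRSF10, and the groups used here follow the genotype label, which the SRSF10 levels match in all 6 libraries. The knockdown samples are titled SH1 to SH3 but described as SRSF10SH2_1 to SRSF10SH2_3, and the controls are titled NC1 to NC3. These names do not settle whether the knockdowns share a single construct. An effect of a single construct or clone therefore cannot be told apart from loss of SRSF10.

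RNA encoded by the mitochondrial genome took a larger part of the reads after knockdown. Its share was 9.99 ± 0.34% of assigned reads in the controls and 16.5 ± 2.0% in the knockdowns (SD, n = 3), and the lowest knockdown, at 14.4%, lay above the highest control, at 10.3%. Because RPKM is relative to all assigned reads, this share moves with the groups beside every other gene group described here. The 10 most abundant genes took 10.95 ± 0.19% of reads in the controls and 15.5 ± 1.62% in the knockdowns.

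**Figure D1:**
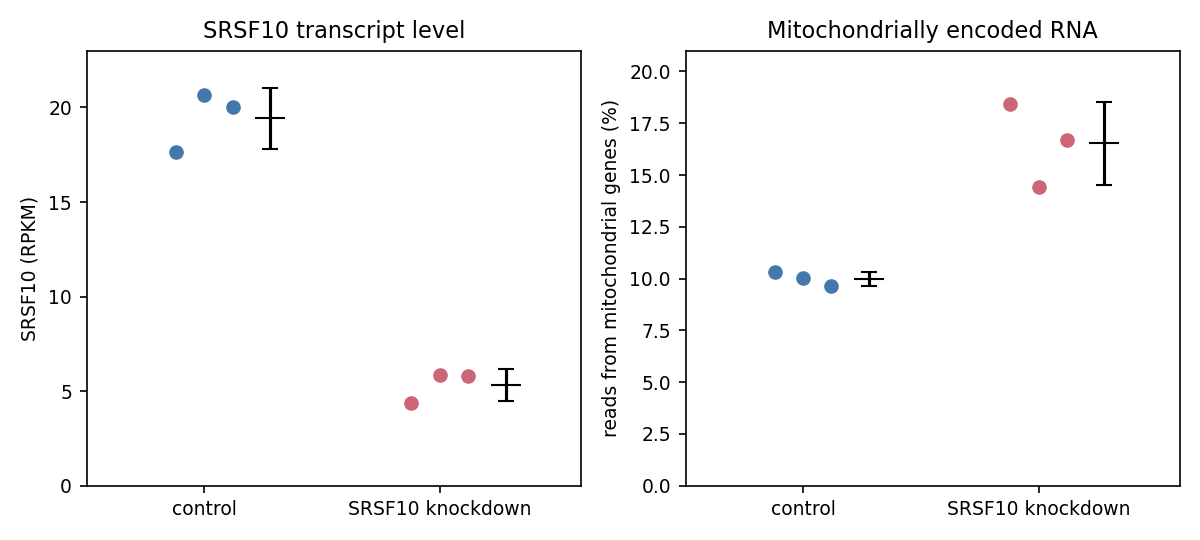
SRSF10 level in RPKM (left) and the percentage of assigned reads from mitochondrial genes (right) in each of the 3 control and 3 SRSF10 knockdown libraries; points are libraries and bars show the mean ± SD. SRSF10 was 17.6 to 20.7 RPKM in the controls and 4.37 to 5.83 RPKM in the knockdowns, and the mitochondrial share was 9.65 to 10.3% against 14.4 to 18.4%.

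The genes with the largest decreases included RUNX2, a transcription factor of bone formation and haematopoietic cells, which fell from 3.85 ± 0.382 to 0.491 ± 0.0787 RPKM (log2 fold change −2.13, SE 0.103, limma adjusted p = 8.9e-05). NCAM1, the adhesion molecule CD56, fell from 25.1 ± 0.946 to 6.47 ± 0.379 RPKM (−1.88, SE 0.071, adjusted p = 6.21e-05). BHLHE22, a basic helix-loop-helix transcription factor, fell from 2.25 ± 0.0894 to 0.168 ± 0.0395 RPKM, and TES, a focal adhesion protein, fell from 10.3 ± 1.11 to 2.68 ± 0.792 RPKM. SIGLEC6, a sialic acid-binding lectin, fell from 1.35 ± 0.226 to 0.0658 ± 0.0771 RPKM. Among the largest increases, TAF7L, a paralogue of the TFIID subunit TAF7, rose from 0.222 ± 0.0436 to 1.85 ± 0.388 RPKM (log2 fold change 1.69, SE 0.129, adjusted p = 0.000303), and CIB3, a calcium- and integrin-binding protein, rose from 1.87 ± 0.284 to 7.07 ± 0.705 RPKM (1.68, SE 0.115, adjusted p = 0.000254). VSIG2 rose from 1.35 ± 0.0844 to 4.63 ± 0.107 RPKM, the neurotrophic ligand ARTN from 1.89 ± 0.133 to 5.80 ± 0.569 RPKM and the mitochondrial carrier UCP3 from 1.05 ± 0.0789 to 3.44 ± 0.253 RPKM.

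RUNX2 lies on chromosome 6 from 45328157 to 45664349 and NCAM1 on chromosome 11 from 112961247 to 113278436, both on the plus strand (GRCh38). The lncRNA NCAM1-AS1 fell by 2.14 on the log2 scale, from 27.8 ± 2.7 to 5.93 ± 0.495 RPKM, but 46.1% of its exon sequence overlaps NCAM1 and the strand used in counting is not given in the sources used here, so its reads cannot be separated from those of NCAM1. The same limit applies to SMARCA5-AS1 (log2 fold change −1.94, 66.7% overlap with SMARCA5), RAD21-AS1 (−1.94, 18% overlap with RAD21) and MCM8-AS1 (1.38, 15.8% overlap with another transcript). It also applies to the small nucleolar RNA SNORD34, which lies wholly inside RPL13A (1.56, from 8 to 40 reads per library). The remaining genes chosen by size were C6orf223 (−1.72) and the microRNA gene MIR222 (−1.71) among those that fell, and PAQR6 (1.38), CYSRT1 (1.32) and the mitochondrial isoleucine tRNA MT-TI (1.39) among those that rose. MIR222 rested on 6 to 65 reads per library, and its adjusted p of 0.0253 in limma became 0.059, 0.088 and 0.068 without control 2, control 3 and knockdown 3.

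**Figure D2:**
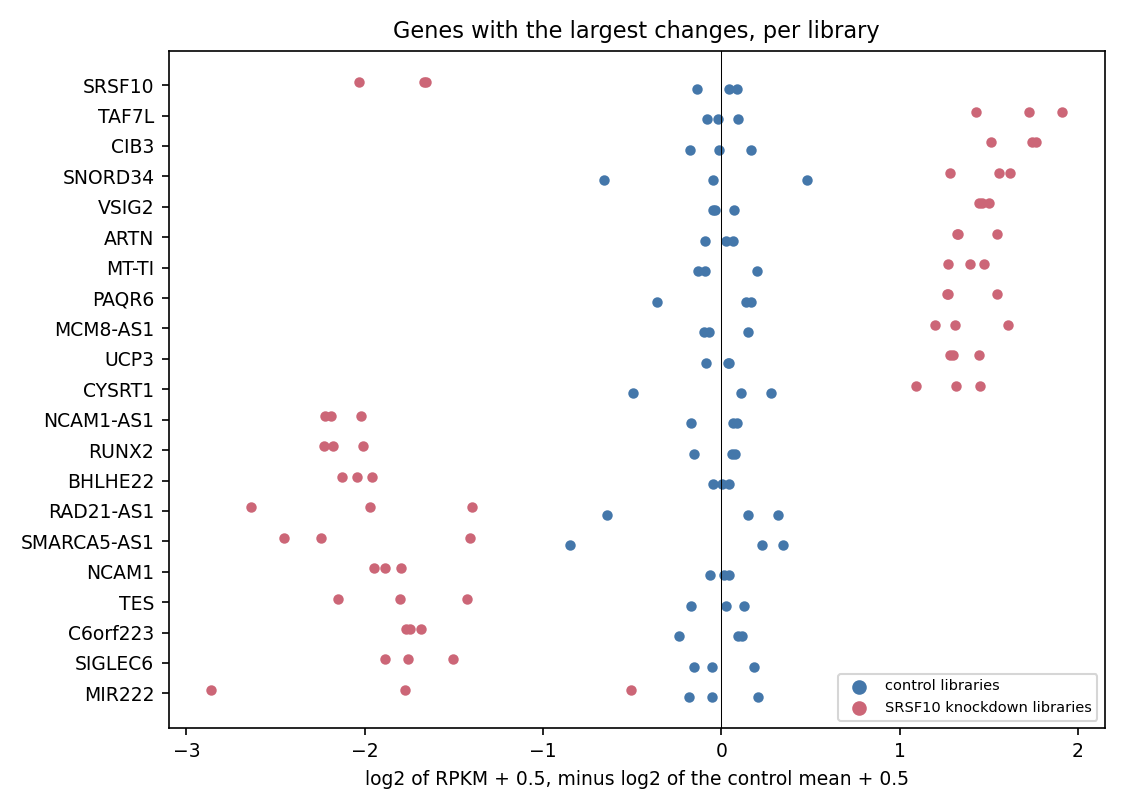
Log2 of RPKM + 0.5 for SRSF10 and the 10 genes with the largest increase and the 10 with the largest decrease, each minus the log2 of its control mean + 0.5; each point is 1 of the 3 control (blue) or 3 knockdown (red) libraries. In all 21 genes every knockdown library lies on the same side of every control library, which the rule of choice required of all but SRSF10.

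Across the 14223 genes tested, 6284 differed between the groups at an adjusted p under 0.05 (limma, Benjamini-Hochberg), of which 2112 were higher and 4172 lower in the knockdown. At least 2-fold changes were found for 324 of them, 104 higher and 220 lower. When only the 10660 genes annotated as protein-coding were tested, 120 passed with at least a 2-fold change, a smaller share than among all genes tested. The division into higher and lower depends on the scaling. The median gene had a log2 fold change of −0.096 in RPKM, and when each library was centred on its median gene 6172 genes passed, 3150 higher and 3022 lower. Quantile normalisation gave 3120 higher and 3131 lower, and scaling to non-mitochondrial reads, chosen after seeing the data, gave 3115 higher and 3016 lower. After a correction for GC content and gene length, also chosen after seeing the data, 3219 were higher and 3085 lower. Gene groups are therefore given below both in RPKM and relative to the median gene. The count of genes in a group that fell or rose is to be read against these totals. Of the 14223 genes 4172 fell and 2112 rose in RPKM, and of the 10660 protein-coding genes tested alone 3615 fell and 1569 rose. Without control 2, control 3 or knockdown 3, 3804, 3534 and 3808 genes passed, and without control 1 or knockdown 2 the 2-fold count was 492 and 501.

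**Figure D3:**
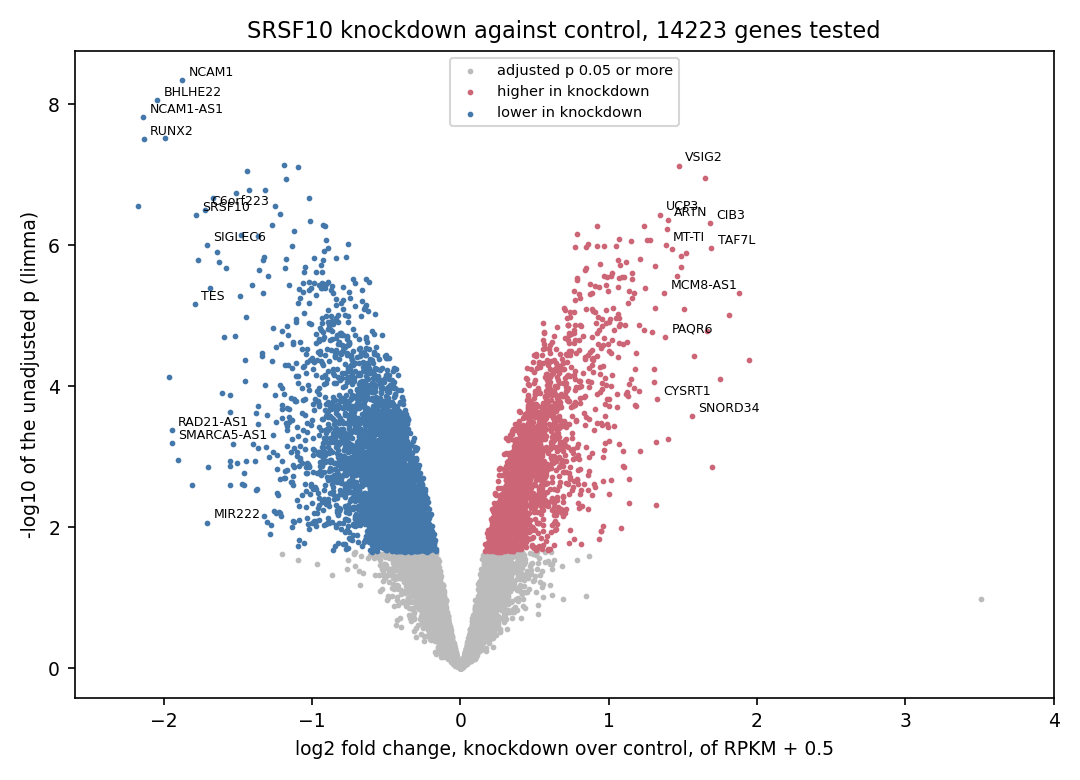
Each point is 1 of 14223 genes, with the log2 fold change of RPKM + 0.5 (knockdown over control, n = 3 libraries each) on the horizontal axis and −log10 of the unadjusted limma p on the vertical axis. Red and blue points are the 2112 higher and 4172 lower genes with an adjusted p under 0.05, and the labels mark SRSF10 and the genes with the largest changes.

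In 2909 genes every knockdown library lay above every control and in 5146 every knockdown lay below, together 56.6% of the genes tested where chance gives 10%. The authors' deposited table lists 7084 genes with an FDR under 0.05, 3500 higher and 3584 lower, and 902 of them at least 2-fold changed. Of the 6284 genes called here, 5364 had an FDR under 0.05 in the authors' deposited table with the same direction, none had the opposite direction and 920 were not called there. Among the genes tested here, 6575 had such an FDR in that table, and 1211 of these were called only there. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Spearman rho of 0.994, and the values in the authors' deposited table were higher by a median of 0.115. Without control 2 and without control 3 the calls shared with that table numbered 3555 and 3381.

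All 13 mitochondrially encoded mRNAs, which code for subunits of the respiratory chain and ATP synthase, rose, in RPKM and relative to the median gene. MT-ND1 went from 10520 ± 518 to 20230 ± 2350 RPKM (log2 fold change 0.94, SE 0.12), MT-ND2 from 4503 ± 360 to 8819 ± 1180 RPKM and MT-CO2 from 3548 ± 182 to 6373 ± 648 RPKM. All 13 also passed when adjusted over the list alone. Camera with a preset correlation of 0.01 gave the list an adjusted p of 1.44e-08 (limma), and the call was lost at an adjusted p = 0.69 with an estimated correlation. Quantile normalisation, which gives every library the same highest values, took the median of the list relative to all genes from 0.76 to 0 and ended the call, at an adjusted p of 0.48.

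Of the 40 nuclear genes of oxidative phosphorylation, 9 rose, 8 fell and 23 did not pass the test, and the list was not called (camera adjusted p = 0.113, limma). NDUFS1, a complex I subunit, fell from 3.74 ± 0.209 to 2.58 ± 0.192 RPKM and the ATP synthase gene ATP5G1 rose from 7.63 ± 0.837 to 10.4 ± 0.531 RPKM. COX4I1, at 146 ± 8.61 and 166 ± 8.5 RPKM, did not pass (adjusted p = 0.0596). Relative to the median gene 14 rose and 3 fell, and adjusted over the list alone the counts were 9 and 8. Without control 2, control 3, knockdown 1 and knockdown 3 in turn, 2, 2, 3 and 1 rose and 2, 3, 2 and 2 fell.

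Of 49 ribosomal protein genes, 12 rose, 1 fell and 36 did not pass. RPS24 rose from 262 ± 41.4 to 420 ± 50.6 RPKM, RPS19 from 109 ± 15.5 to 159 ± 15.8 RPKM and RPL18 from 34.1 ± 2.91 to 43.6 ± 1.93 RPKM. RPL5, at 1547 ± 96.4 and 1751 ± 99.9 RPKM, did not pass (adjusted p = 0.113). Camera called the list up (adjusted p = 1.94e-05, limma), a call lost at an adjusted p = 0.77 with an estimated correlation and at 0.11 after quantile normalisation. Adjusted over the list alone 4 rose and none fell, and relative to the median gene 18 rose and none fell. The controls differed in this list, with a median of 0.15 in control 1 and −0.12 in control 2 against 0.09 to 0.21 in the knockdowns (log2, relative to the control mean of each gene). Without control 1 the list had 29 that rose, and without control 2, control 3, knockdown 1 or knockdown 3 it had 4, 3, 4 and 4, and none fell without control 3, knockdown 1 or knockdown 3. Of 30 genes of ribosome biogenesis and MYC targets, 7 rose and 9 fell, also adjusted over the list alone, with no call (camera adjusted p = 0.427). Nucleolin, NCL, fell from 1132 ± 81.4 to 802 ± 110 RPKM, while NOP56 rose from 53.5 ± 4.92 to 71.6 ± 5.25 RPKM. Relative to the median gene 10 rose and 3 fell, and the counts were 2 and 2 without control 2, control 3 or knockdown 3 and 3 and 3 without knockdown 1.

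Genes of cholesterol synthesis fell together. Of the 21 measured, 18 fell and none rose, with 19 falling when adjusted over the list alone and 16 relative to the median gene. LSS, lanosterol synthase, fell from 3.48 ± 0.222 to 1.76 ± 0.178 RPKM (log2 fold change −0.82, SE 0.094, limma adjusted p = 0.00117). DHCR7, which makes cholesterol from its last precursor, fell from 2.72 ± 0.234 to 1.30 ± 0.165 RPKM, and CYP51A1 from 7.75 ± 0.566 to 4.25 ± 0.589 RPKM, although 78.8% of its exon sequence overlaps LRRD1. FDPS, at 74.3 ± 5.35 and 65.0 ± 0.743 RPKM, did not pass (adjusted p = 0.0538). The median of the list was −0.79, −0.48 and −0.64 in knockdowns 1 to 3 and −0.09 to 0.07 in the controls. Camera gave an adjusted p of 1.94e-05, and the call was lost at an adjusted p = 0.69 with an estimated correlation.

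Among 18 genes of fatty acid metabolism and lipid storage, 6 fell and 2 rose, with 7 and 2 adjusted over the list alone and 6 and 2 relative to the median gene (camera adjusted p = 0.236). ACLY, ATP citrate lyase, fell from 26.0 ± 3.53 to 13.96 ± 2.8 RPKM, ACADM from 13.2 ± 1.82 to 7.48 ± 1.36 RPKM and the desaturase SCD from 21.8 ± 1.28 to 15.5 ± 1.28 RPKM. FABP5 gave 194 ± 7.6 and 183 ± 17.6 RPKM and did not pass. Without control 2, control 3, knockdown 1 or knockdown 3, 1 of these genes rose.

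Genes of the hypoxia response were lower in the knockdown: 10 of 13 fell and none rose, in RPKM, relative to the median gene and adjusted over the list alone. The angiogenic factor VEGFA fell from 12.5 ± 0.347 to 6.49 ± 0.276 RPKM (log2 fold change −0.89, SE 0.068, limma adjusted p = 0.000303), NDRG1 from 8.75 ± 0.747 to 5.60 ± 0.175 RPKM and the mitophagy receptor BNIP3 from 8.62 ± 0.145 to 5.14 ± 0.788 RPKM. ERO1A did not pass, at 1.81 ± 0.263 and 2.05 ± 0.123 RPKM. Camera called the list down at an adjusted p of 0.00599, a call lost at an adjusted p = 0.69 with an estimated correlation. Of 19 glycolysis genes, 10 fell and 1 rose, also adjusted over the list alone, and 4 fell and 1 rose relative to the median gene (camera adjusted p = 0.104). PGK1 fell from 24.7 ± 3.5 to 13.5 ± 2.52 RPKM, PFKL from 13.04 ± 1.17 to 8.42 ± 0.781 RPKM and PGAM1 from 56.4 ± 4.97 to 40.8 ± 4.78 RPKM, while ENO1 did not pass at 274 ± 23.6 and 239 ± 34.1 RPKM. Glycolysis genes that fell numbered 5, 4, 5 and 5 without control 2, control 3, knockdown 1 and knockdown 3, and none rose when any 1 of these 4 was left out.

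Genes of the G2 and M phases of the cell cycle fell as a group. Of 37 measured, 24 fell and 1 rose, also adjusted over the list alone, and 23 fell and 1 rose relative to the median gene. CCNB1, cyclin B1, fell from 45.8 ± 2.29 to 26.9 ± 2.76 RPKM (log2 fold change −0.76, SE 0.085, limma adjusted p = 0.00107). The spindle checkpoint kinase TTK fell from 6.59 ± 0.693 to 3.11 ± 0.349 RPKM and the kinetochore protein CENPF from 39.6 ± 3.47 to 21.4 ± 2.45 RPKM. NUSAP1 did not pass, at 98.7 ± 3.18 and 89.7 ± 2.15 RPKM. No gene of this list rose without control 2, control 3, knockdown 1, knockdown 2 or knockdown 3. Camera gave an adjusted p of 1.94e-05, and the call was lost at an adjusted p = 0.69 with an estimated correlation.

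The 36 genes of the G1 to S transition moved in both directions, with 6 rising and 11 falling, also adjusted over the list alone, and 8 each way relative to the median gene (camera adjusted p = 0.875). FEN1, the flap endonuclease, rose from 68.1 ± 3.34 to 96.9 ± 2.17 RPKM and CCNE1, cyclin E1, from 6.43 ± 0.338 to 9.91 ± 0.61 RPKM. TYMS did not pass, at 166 ± 3.45 and 152 ± 11.3 RPKM. The number that fell was 5, 4, 6 and 4 without control 2, control 3, knockdown 1 and knockdown 3. Of 26 genes of DNA damage response and repair, 15 fell and 1 rose, with 16 and 3 adjusted over the list alone and 7 and 4 relative to the median gene (camera adjusted p = 0.137). RAD50 fell from 11.6 ± 0.631 to 8.13 ± 0.611 RPKM and XRCC5 from 53.7 ± 2.4 to 42.1 ± 3.08 RPKM. Without those same 4 libraries in turn, 6, 5, 7 and 5 repair genes fell and none rose, and without control 1, 3 rose.

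Of 18 p53 target genes, 7 fell and 1 rose, with 7 and 3 adjusted over the list alone and 4 and 3 relative to the median gene (camera adjusted p = 0.628). SESN2 fell from 6.00 ± 0.718 to 3.36 ± 0.214 RPKM and SESN1 from 1.59 ± 0.0482 to 0.824 ± 0.131 RPKM, whereas the growth arrest gene GADD45A rose from 15.6 ± 1.03 to 22.3 ± 1.51 RPKM. Only 3 p53 targets fell without control 2, control 3, knockdown 1 or knockdown 3, and 3 rose without control 1. Of 13 BCL2 family genes, 3 fell and 1 rose, also adjusted over the list alone, and 3 fell and 3 rose relative to the median gene (camera adjusted p = 0.793). MCL1, an inhibitor of apoptosis, fell from 22.5 ± 2.99 to 14.7 ± 2.21 RPKM, BIK fell from 7.65 ± 0.792 to 5.66 ± 0.35 RPKM and BMF rose from 1.09 ± 0.0607 to 1.55 ± 0.235 RPKM. The BIK call was lost without knockdown 3 (adjusted p = 0.053) and the BMF call without control 2 (0.071), control 3 (0.078) or knockdown 1 (0.056). The number of BCL2 family genes that fell was 1 without knockdown 3 and 5 without knockdown 2, and 2 rose without control 1. BAX did not pass at 15.5 ± 1.87 and 18.7 ± 1.31 RPKM. Of 4 CDK inhibitors tested, CDKN2C fell from 59.8 ± 4.29 to 48.9 ± 6.31 RPKM (adjusted p = 0.0471, 0.0956 relative to the median gene, and 0.13, 0.14, 0.13 and 0.12 without control 2, control 3, knockdown 1 and knockdown 3), and none passed when adjusted over the list alone. Relative to the median gene none fell and 1 rose, CDKN2D (adjusted p = 0.0473), which in RPKM did not pass at 9.66 ± 1.05 and 11.05 ± 0.621.

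The kinases and phosphatases that act on splicing factors were lower: 6 of 11 fell and none rose, also adjusted over the list alone, and 5 fell relative to the median gene. SRPK1, an SR protein kinase, fell from 14.7 ± 1.96 to 7.24 ± 1.37 RPKM (log2 fold change −0.98, SE 0.145, limma adjusted p = 0.00283), SRPK2 from 4.97 ± 0.494 to 2.62 ± 0.535 RPKM and CLK4 from 4.52 ± 0.131 to 3.28 ± 0.153 RPKM. CLK2 did not pass, at 55.4 ± 2.52 and 51.7 ± 2.99 RPKM. Camera called the list down at an adjusted p of 0.0341, lost at an adjusted p = 0.77 with an estimated correlation. After the correction for GC content and gene length the list had an adjusted p of 0.12 and CLK4 one of 0.099.

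Other splicing factors changed in both directions. Of the 12 other SR proteins measured, 3 fell and 1 rose, with 2 and 1 adjusted over the list alone, whereas relative to the median gene none fell and 3 rose (camera adjusted p = 0.926). SRSF6 fell from 54.9 ± 0.532 to 47.0 ± 1.02 RPKM and TRA2B from 25.3 ± 0.473 to 20.98 ± 2.14 RPKM, and TRA2A rose from 19.8 ± 1.42 to 24.0 ± 0.68 RPKM. The SRSF6 and TRA2B calls were lost relative to the median gene (adjusted p = 0.132 and 0.0752), the TRA2A call was lost without control 2 (0.053), and no SR protein passed without control 3 or knockdown 3. Without control 2 or knockdown 1, 1 SR protein fell, and TRA2B did not pass (0.084 and 0.085). Of 23 hnRNP proteins, 14 fell and 3 rose, with 17 and 3 adjusted over the list alone and 8 and 4 relative to the median gene (camera adjusted p = 0.0763). SYNCRIP fell from 79.8 ± 8.69 to 46.6 ± 6.11 RPKM, HNRNPR from 64.3 ± 6.36 to 36.6 ± 6.14 RPKM and HNRNPUL2 from 83.0 ± 4.71 to 56.9 ± 3.04 RPKM, with 44.5% of the exon sequence of HNRNPUL2 shared with a read-through transcript. Without control 2 and without knockdown 3, 8 and 7 hnRNP genes fell, and without control 3 or knockdown 3 only 1 rose. Of 35 core spliceosome genes, 13 fell and 7 rose, also adjusted over the list alone, and 10 fell and 11 rose relative to the median gene (camera adjusted p = 0.866). CDC5L fell from 19.6 ± 1.47 to 11.02 ± 1.26 RPKM, PRPF8 from 9.53 ± 1.13 to 5.87 ± 0.76 RPKM and the helicase SNRNP200 from 25.2 ± 2.72 to 17.5 ± 0.924 RPKM. Without knockdown 3, 8 core spliceosome genes fell and 5 rose.

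Of 9 genes whose splicing has been reported to depend on SRSF10, 3 fell and none rose, in RPKM, relative to the median gene and adjusted over the list alone (camera adjusted p = 0.117). BCLAF1, an apoptosis-related transcription regulator, fell from 28.1 ± 2.73 to 14.4 ± 1.58 RPKM (log2 fold change −0.95, SE 0.102, limma adjusted p = 0.000942), the phosphatase CDC25B from 9.67 ± 0.738 to 6.29 ± 0.0142 RPKM and the chaperone HSPA8 from 477 ± 31.3 to 346 ± 3.53 RPKM. PKM, pyruvate kinase, did not pass at 74.6 ± 3.84 and 70.0 ± 8.06 RPKM. Gene-level RPKM does not show which exons were used, so splicing itself was not measured here. Of 14 nonsense-mediated decay factors, 4 fell, none passed when adjusted over the list alone, and 1 fell and 2 rose relative to the median gene (camera adjusted p = 0.845). CASC3 fell from 17.1 ± 3.57 to 8.92 ± 2.84 RPKM, a call lost without control 2 (adjusted p = 0.06) or control 3 (0.065). No decay factor passed without control 2 or control 3, 1 fell without knockdown 1 or knockdown 3, and 2 fell without control 1.

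Markers of granulocytes and neutrophils rose, several of which THP-1 cells also express: 6 of the 9 measured rose and none fell, also adjusted over the list alone, and 7 rose relative to the median gene. The calcium-binding protein S100A9 rose from 22.4 ± 0.714 to 45.8 ± 8.55 RPKM (log2 fold change 1.001, SE 0.119, limma adjusted p = 0.00134), neutrophil elastase, ELANE, from 154 ± 6.23 to 241 ± 24.1 RPKM and myeloperoxidase, MPO, from 2.22 ± 0.134 to 3.70 ± 0.17 RPKM. Proteinase 3, PRTN3, did not pass at 414 ± 37.9 and 447 ± 20.1 RPKM. Camera called the list up at an adjusted p of 0.00029, a call lost at an adjusted p = 0.435 with an estimated correlation.

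The 16 genes of monocyte and macrophage differentiation did not move one way, with 7 rising and 4 falling, also adjusted over the list alone, and 7 and 2 relative to the median gene (camera adjusted p = 0.217). The lysosomal protease CTSD rose from 19.5 ± 0.678 to 35.6 ± 2.37 RPKM and the integrin ITGAX, CD11c, from 3.20 ± 0.317 to 6.00 ± 0.19 RPKM. CD68, a macrophage glycoprotein, fell from 86.9 ± 6.78 to 42.3 ± 7.49 RPKM (log2 fold change −1.04, SE 0.126, limma adjusted p = 0.00139), with 81.7% of its exon sequence overlapping another transcript. Lysozyme, LYZ, did not pass at 63.4 ± 2.8 and 59.5 ± 6.03 RPKM. Without control 2, control 3 or knockdown 1, 2 of these genes fell.

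Of 14 myeloid transcription factors, 6 fell and 4 rose, with 7 and 4 adjusted over the list alone and 5 and 4 relative to the median gene (camera adjusted p = 0.63). GATA2, a factor of haematopoietic progenitors, fell from 8.58 ± 0.473 to 4.08 ± 0.228 RPKM, EGR1 from 3.12 ± 0.0662 to 1.29 ± 0.165 RPKM and KLF4 from 2.04 ± 0.0566 to 1.14 ± 0.0365 RPKM. MYC did not pass, at 64.5 ± 1.16 and 61.6 ± 1.61 RPKM. None of these factors rose without control 3 or knockdown 3, 1 rose without control 2 or knockdown 1, 2 rose without knockdown 2, and 3 fell without knockdown 3. Of 10 genes of the leukaemia stem cell and HOX programme, 5 fell and 1 rose, also adjusted over the list alone, and 4 and 2 relative to the median gene (camera adjusted p = 0.552). MEF2C fell from 4.84 ± 0.882 to 2.09 ± 0.475 RPKM, PBX3 from 14.9 ± 1.54 to 10.3 ± 0.899 RPKM and the receptor FLT3 from 11.4 ± 0.891 to 8.40 ± 0.613 RPKM, while HOXA9 did not pass at 9.76 ± 0.74 and 9.55 ± 0.812 RPKM. Without control 2, control 3, knockdown 1 or knockdown 3, 3 genes of this programme fell.

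Of 14 NF-kB and inflammatory cytokine genes, 6 fell and 1 rose, also adjusted over the list alone, and 4 each way relative to the median gene (camera adjusted p = 0.57). TNF fell from 4.18 ± 0.361 to 1.56 ± 0.163 RPKM (log2 fold change −1.18, SE 0.098, limma adjusted p = 0.000388) and NFKB2 from 7.65 ± 0.473 to 5.37 ± 0.167 RPKM, whereas IL1RN, the interleukin-1 receptor antagonist, rose from 1.96 ± 0.161 to 3.20 ± 0.257 RPKM. CCL5 did not pass, at 30.3 ± 2.52 and 26.5 ± 1.53 RPKM. Of 25 interferon-stimulated genes, 11 fell and 1 rose, also adjusted over the list alone, and 8 and 3 relative to the median gene (camera adjusted p = 0.236). XAF1 fell from 10.2 ± 0.36 to 6.98 ± 0.435 RPKM and IRF7 from 1.89 ± 0.171 to 1.23 ± 0.0659 RPKM, and BST2 did not pass at 218 ± 2.21 and 246 ± 18.8 RPKM. Without control 2 or knockdown 1, 7 interferon-stimulated genes fell, and without control 1, 2 rose.

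Antigen presentation genes were mixed. Of 7 MHC class II genes, 1 rose and 1 fell, also adjusted over the list alone, and 2 rose and 1 fell relative to the median gene (camera adjusted p = 0.607). CD74, the invariant chain, rose from 56.7 ± 2.01 to 84.2 ± 3.57 RPKM and HLA-DRB1 fell from 34.4 ± 1.09 to 28.3 ± 0.919 RPKM. Of 13 MHC class I genes, 3 rose and 2 fell, with 2 each way adjusted over the list alone and 4 and 2 relative to the median gene (camera adjusted p = 0.368). HLA-E fell from 39.4 ± 1.52 to 29.5 ± 2.13 RPKM. HLA genes are similar in sequence and their reads may have been split between them, and without control 2, control 3, knockdown 2 or knockdown 3 only 1 class I gene rose. Only 1 class I gene fell without control 2, control 3, knockdown 1 or knockdown 3.

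Of 18 adhesion and migration genes, 11 fell and 3 rose, also adjusted over the list alone, and 10 and 4 relative to the median gene. The membrane protease MMP14 fell from 65.4 ± 0.773 to 38.4 ± 1.17 RPKM (log2 fold change −0.76, SE 0.057, limma adjusted p = 0.000303), the integrin ITGAL from 11.4 ± 0.374 to 5.80 ± 0.291 RPKM and PECAM1 from 19.8 ± 0.316 to 12.6 ± 0.436 RPKM. The list was not called in RPKM (camera adjusted p = 0.0763, and adjusted p = 0.69 with an estimated correlation) and was called down after median centring (0.0434). Of 14 MAPK feedback and immediate early genes, 5 fell and 1 rose, also adjusted over the list alone, and 2 fell and 3 rose relative to the median gene (camera adjusted p = 0.793). FOS fell from 5.54 ± 0.464 to 3.09 ± 0.138 RPKM and JUND did not pass, at 14.6 ± 1.74 and 14.6 ± 0.904 RPKM. Only 2 MAPK feedback genes fell without control 2, control 3, knockdown 1 or knockdown 3, and none rose when any 1 of the 6 libraries was left out.

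Of 26 genes of the unfolded protein response and the ATF4 programme, 14 fell and 3 rose, also adjusted over the list alone, and 14 and 4 relative to the median gene. PHGDH, the first enzyme of serine synthesis, fell from 62.5 ± 3.8 to 34.2 ± 2.45 RPKM (log2 fold change −0.86, SE 0.077, limma adjusted p = 0.000477), PSAT1, of the same pathway, from 23.1 ± 1.62 to 11.2 ± 1.61 RPKM and TRIB3 from 6.15 ± 0.659 to 3.43 ± 0.245 RPKM. HSP90B1 did not pass, at 449 ± 10.8 and 432 ± 24.2 RPKM. The list was not called in RPKM (camera adjusted p = 0.0675, and adjusted p = 0.736 with an estimated correlation) and was called down after median centring (0.0434), without control 2 (0.04) and without knockdown 1 (0.034). Of 13 heat shock proteins, 7 fell and none rose, with 8 adjusted over the list alone and 7 relative to the median gene. HSP90AB1 fell from 1775 ± 83.4 to 1152 ± 131 RPKM and BAG3 from 17.2 ± 0.273 to 13.3 ± 0.279 RPKM, and HSPD1 did not pass at 151 ± 4.82 and 139 ± 2.98 RPKM. Camera called the heat shock list down at an adjusted p of 0.0471, lost at an adjusted p = 0.69 with an estimated correlation, at 0.0664 after median centring, and without control 1 (0.063), control 3 (0.054), knockdown 2 (0.066) or knockdown 3 (0.066).

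Of 18 genes of oxidative stress and iron handling, 4 rose and 3 fell, also adjusted over the list alone, and 7 and 2 relative to the median gene (camera adjusted p = 0.0848). The ferritin chains FTH1 and FTL rose from 155 ± 11.8 to 256 ± 10.2 RPKM and from 206 ± 8.31 to 346 ± 33.6 RPKM, with 62.4% of the FTH1 exon sequence overlapping BEST1, and PRDX1 rose from 111 ± 4.49 to 154 ± 4.69 RPKM. GPX4 did not pass, at 187 ± 12.5 and 182 ± 14.1 RPKM. Of 25 lysosome and autophagy genes, 4 fell and 1 rose, with 2 and 1 adjusted over the list alone and 2 and 3 relative to the median gene (camera adjusted p = 0.841). MCOLN1, a lysosomal channel, fell from 2.97 ± 0.175 to 2.06 ± 0.149 RPKM, and CTSZ did not pass at 73.1 ± 1.13 and 68.2 ± 2.29 RPKM. In each of these 2 lists 1 gene fell without control 2, control 3, knockdown 1 or knockdown 3.

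Markers of other blood cell types were too few to test as lists. Of 3 T and NK cell markers, TRAC fell from 1.06 ± 0.145 to 0.319 ± 0.116 RPKM and CD4, which monocytes also express, from 4.32 ± 0.738 to 2.76 ± 0.38 RPKM, and NKG7 at 6.86 ± 0.99 and 8.62 ± 0.684 RPKM did not pass over all genes in RPKM (adjusted p = 0.0512) but rose adjusted over the list alone and relative to the median gene (0.026). The CD4 call was lost without control 2 (adjusted p = 0.055) or control 3 (0.061). Of 4 dendritic cell markers 2 rose and 1 fell, also adjusted over the list alone: IL3RA went from 6.94 ± 0.245 to 10.03 ± 0.555 RPKM, CD83 from 2.76 ± 0.128 to 3.49 ± 0.243 RPKM and FLT3 was the marker that fell. The CD83 call was lost without control 1 (adjusted p = 0.057), control 2 (0.053), control 3 (0.075), knockdown 2 (0.064) or knockdown 3 (0.069). Of 3 megakaryocyte and platelet markers 1 rose, GP1BB, from 6.38 ± 0.943 to 12.1 ± 0.671 RPKM, whose exon sequence overlaps SEPT5 in full. No epithelial or fibroblast marker reached the level needed for a test. The only replication-dependent histone gene tested, HIST1H1C, rose from 5.06 ± 0.844 to 8.54 ± 0.607 RPKM. Neither of the 2 erythroid markers passed in RPKM, and relative to the median gene EPOR rose (adjusted p = 0.0492). The globin gene HBA2 stood at 468 RPKM in knockdown 3 and at 0.48 to 1.98 RPKM in the other 5 libraries, and the source of those reads was not determined.

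**Figure D4:**
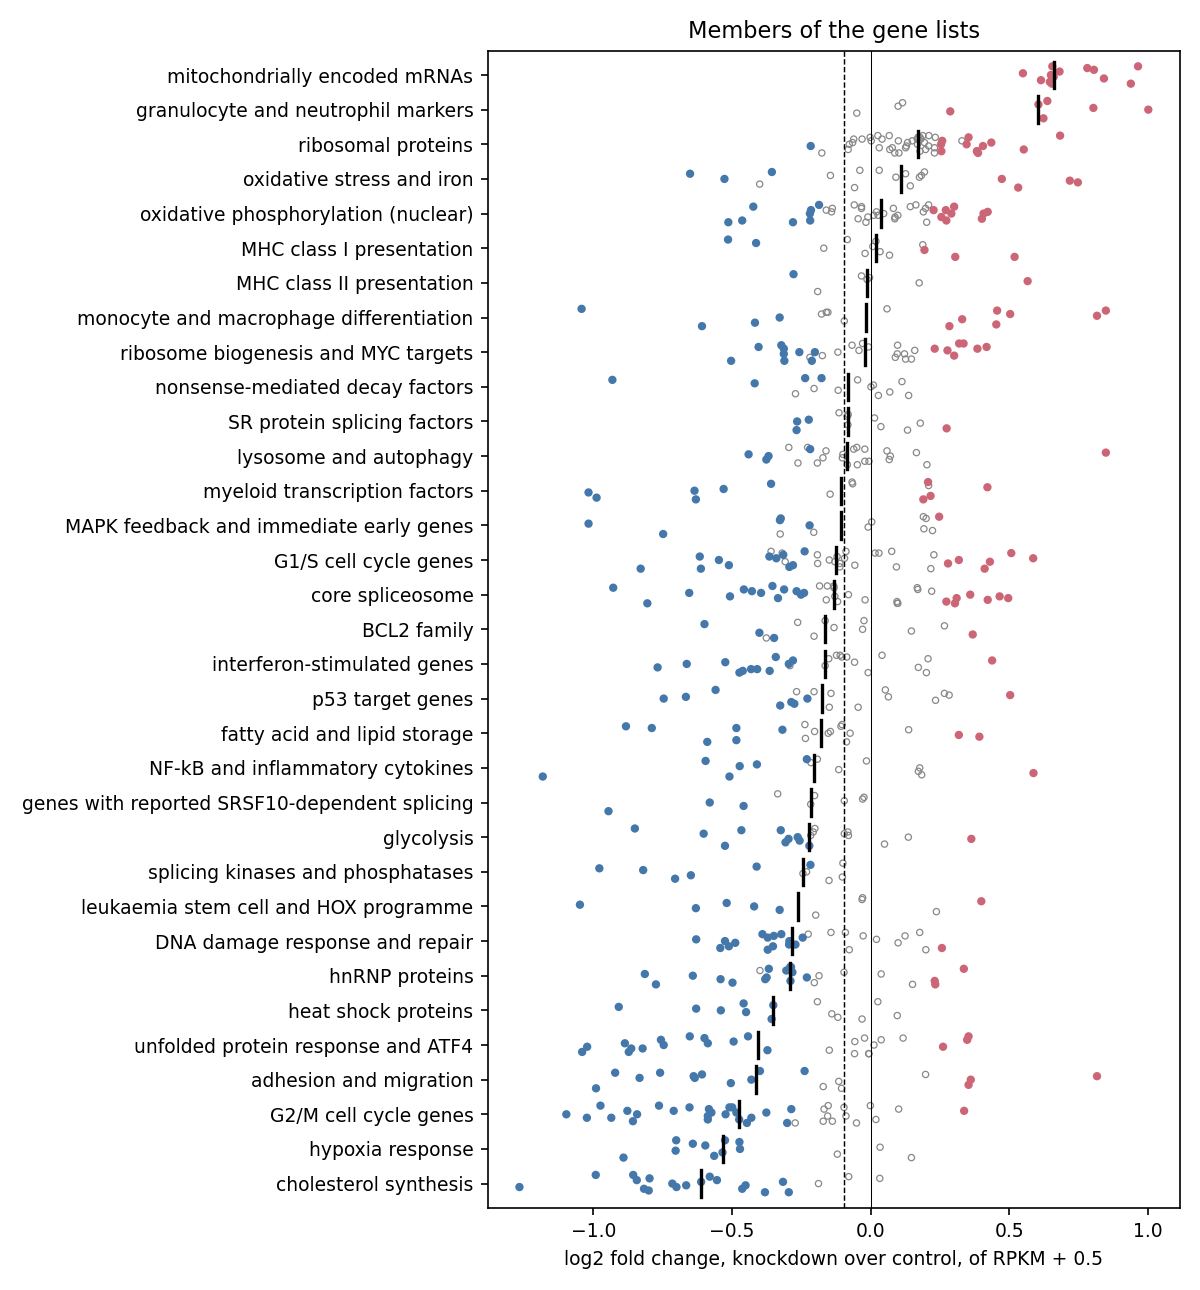
Log2 fold change of RPKM + 0.5 (knockdown over control, n = 3 libraries each) for each member of the 33 gene lists with at least 5 tested members. Filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, black bars are list medians, from −0.61 for cholesterol synthesis to 0.66 for mitochondrially encoded mRNAs, and the dashed line marks the median of all genes at −0.096.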

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

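The limma-voom fit, the non-mitochondrial scaling and the GC and length correction were chosen after seeing the data. SRSF10 kept its direction and passed the threshold under every alternative run, and no named gene or called list changed sign and passed under any. The count of 6284 changed genes stayed within 1.5 times except when single libraries were left out, with a range of 3534 to 6748. The 2-fold count of 324 became 614 with a pseudocount of 0.1, 197 with a pseudocount of 1 and 210 with at least 1 RPKM in all 6 libraries. It was 120 for the 10660 protein-coding genes alone, a smaller share of the genes tested than in the main fit. Limma-voom on recovered reads gave a 2-fold count of 739 and called 6534 genes in all. The 2-fold count ranged from 241 to 501 with single libraries left out. The pseudocount acts by shrinking the folds of weakly expressed genes, and for the other changes the cause was not tested. Calls shared with the authors' deposited table ranged from 3381 to 5473 with libraries left out. Of the 8 lists called by camera, 0 were called with an estimated correlation and 21 lists were called by fry. When protein-coding genes alone were tested, 1 of the called lists no longer passed, and a called list was also lost with non-mitochondrial scaling. Of 122 named genes past the threshold, 116 stayed past it with median centring, 117 with quantile normalisation, 115 after the GC and length correction, and 108 to 121 when 1 library was left out, with the same direction. The replicate block called 7798 genes, 326 of them at least 2-fold, and lost the heat shock list (adjusted p = 0.071). Whether the replicate numbers pair the samples was not settled by the check made. Same-numbered libraries deviated together with correlations of 0.48, 0.41 and −0.01. Control 1 with knockdown 2 gave −0.5 and control 2 with knockdown 1 gave −0.4, while control 3 correlated best with knockdown 2, at 0.24. Knockdown 3 gave −0.01 to 0.02 with the controls, so it could not show a pair. With 3 libraries per group, the smallest simulated changes were mostly missed (17.6% recovered), so a gene that did not pass is not shown to be unchanged.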

Other observations

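The gene families in this paragraph and the next were chosen after the fold changes had been seen, and 6 families were tested. Their camera p-values come from those same fold changes and were adjusted over the 6 families only. They describe the families and are not independent evidence. Of 20 cytosolic aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNA, 16 fell and none rose, and relative to the median gene 15 fell and 1 rose. AARS fell from 65.2 ± 4.76 to 29.2 ± 3.81 RPKM (log2 fold change −1.15, SE 0.103, limma adjusted p = 0.000474), NARS from 51.7 ± 8.99 to 24.3 ± 7.41 RPKM and LARS from 21.7 ± 2.51 to 11.98 ± 1.55 RPKM, whereas FARSA, at 103 ± 6.65 and 117 ± 5.4 RPKM, did not pass in RPKM. Camera gave the family an adjusted p of 6.6e-05, lost at an adjusted p = 0.5 with an estimated correlation. Of the 17 mitochondrial synthetases, 3 fell and 1 rose in RPKM and 3 each way relative to the median gene (camera adjusted p = 0.77). CARS2 was the one that rose in RPKM, from 7.09 ± 0.574 to 12.5 ± 0.964 RPKM. The difference between the 2 families was not tested.

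Of 20 cohesin and condensin subunits and their regulators, 10 fell and none rose, in RPKM and relative to the median gene (camera adjusted p = 0.0048, and adjusted p = 0.5 with an estimated correlation). RAD21 fell from 60.9 ± 13.5 to 25.2 ± 9.02 RPKM, the meiotic subunit SMC1B from 3.01 ± 0.139 to 1.23 ± 0.133 RPKM and SMC1A from 41.1 ± 9.78 to 22.0 ± 4.25 RPKM, while PDS5B, at 13.3 ± 0.569 and 13.3 ± 1.21 RPKM, did not pass. Of 43 small nucleolar RNAs, 21 rose and 1 fell, and 23 and 1 relative to the median gene (camera adjusted p = 6.5e-07, and adjusted p = 0.088 with an estimated correlation). SNORA61 rose from 38.8 ± 8.6 to 66.1 ± 8.87 RPKM, but at least 50% of the exon sequence of 30 of the 43 lies within other rows, mostly host genes, so these reads may belong to the hosts. Of 28 genes with kinesin symbols 18 fell and 2 rose, and 14 and 4 relative to the median gene (camera adjusted p = 0.0048, and adjusted p = 0.5 with an estimated correlation). Of 27 clustered protocadherins 26 fell, and 25 relative to the median gene (camera adjusted p = 6.5e-07, and adjusted p = 0.5 with an estimated correlation), although the gamma genes share exons and are not separate measurements.

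Of the tests in the remaining paragraphs, those of the SRSF10 level, of median centring for mitochondrial RNA and both on HBA2 were chosen after the results had been seen. The 10 ways of dividing the 6 libraries into 3 and 3 are too few for a share under 0.05. The real division called 6284 genes and 324 at 2-fold, each the highest of the 10 (1 of 10), and the highest of the others called 0. For lists, 2 of the 10 divisions called as many as the real 8, and the highest of the others also called 8.

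Libraries of 1 group differed from each other along the same genes that separated the groups: across genes, the deviation of control 1 from its group had a Spearman rho of 0.55 with the fold changes, and knockdown 2 had −0.56. A trend with GC content or gene length between libraries is argued against as the whole cause, since rho was still 0.52 after that correction. A different SRSF10 level per library stays open: the order of SRSF10 within the groups went with this axis in 6 of 6 pairs, but 38.6% of the 324 genes changed at least 2-fold did the same. The order along the axis was library 1, then 3, then 2 in both groups. A source shared by libraries of the same number therefore also stays open. Same-numbered libraries deviated together at correlations of 0.48 and 0.41 for numbers 1 and 2, but −0.01 for number 3. The replicate block called 7798 genes against 6284 without it. Neither check settled whether the numbers pair the samples. Whether the axis adds to the fold changes cannot be told apart from knockdown. With the axis estimated from both groups combined and removed, called genes kept a median of 57.4% of their fold change. That is above the 50% set beforehand as arguing against the axis, but the combined estimate was not corrected for noise. Estimates added after that value was seen gave 71.1% from the controls alone and 64.7% from the knockdowns alone. Corrected for noise, these became 44.5% and 36.6%, both under 50%. The axis held 40.1% of the variance of the fold changes across genes, or 57.5% corrected for noise. With the combined estimate of the axis removed, the medians of the 8 called lists relative to all genes went from 0.27 to −0.03 for ribosomal proteins, 0.76 to 0.45 for mitochondrial mRNAs, 0.7 to 0.4 for granulocyte markers, −0.38 to −0.22 for G2 and M genes, −0.51 to −0.35 for cholesterol synthesis, −0.44 to −0.3 for hypoxia genes, −0.25 to −0.21 for heat shock proteins and −0.15 to −0.14 for splicing kinases and phosphatases.

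The rise of the 13 mitochondrially encoded mRNAs was weighed against 3 technical or simple explanations. The authors' scaling of each library by its assigned reads is argued against, since it moves all genes of a library alike and the median log2 change relative to the median gene was 0.77, although quantile normalisation, which gives every library the same highest values, took the difference from all genes from 0.76 to 0. Reads moving from nuclear copies of mitochondrial genes would lower the rows of such copies, but the 13 rows had a median of 0.47, upward like the mRNAs. Those rows may themselves hold reads of the mitochondrial mRNAs and rise with them, so their rise does not decide. A single common rise of all mitochondrial RNA is argued against as the whole account, since 9 of the 13 changed their share of the mitochondrial mRNA reads (limma). These changes were only −0.17 to 0.24 against a median rise of 0.66, and shares of 1 total depend on each other. The rows of the 22 mitochondrial tRNAs all rose with a median of 1.02. Whether their reads came from mature tRNAs or from longer transcripts was not tested. The 2 mitochondrial rRNAs rose by 0.66 and 0.67, near the mRNA median, as a common rise would give. A response to the knockdown and a difference in cell state or RNA preparation between the groups stay open as untested hypotheses.

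HBA2, an alpha globin gene, had 13321 reads in knockdown 3 (468 RPKM) and 16 to 70 reads in each other library. No other gene of the 14223 tested was at least 10-fold higher in any 1 library than in every other library, on RPKM + 0.5. Testing required at least 0.5 RPKM in at least 3 libraries, so genes found in 1 library only were not searched. A swapped library is argued against, since SRSF10 in knockdown 3 was 5.79 RPKM. RNA from red blood cells is a candidate explanation: reads outside the table exceeded the mean of the other 5 libraries by 4.5 of their SD, as other globin reads would give, but those reads carry no gene names. The erythroid receptor gene EPOR, the other erythroid marker tested, was 1.17 RPKM there and 1.01 to 1.30 RPKM elsewhere. Reads assigned to the wrong library during sequencing were not tested, stay open and cannot be separated from such RNA by this excess, and HBA1 is nearly identical to HBA2, so reads of the 2 genes may have been mixed.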
